A study of Homo sapiens with 6 samples.

How the data were processed

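RNA from 6 samples of AGS cells was sequenced, 3 labelled control and 3 labelled EFNA4 knockdown. Groups and replicate numbers come from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, its integrity was measured on a Bioanalyzer, libraries were made with the VAHTS Universal V6 kit, and both ends of fragments were read for 150 bases on a NovaSeq instrument. The authors deposited whole-number counts per gene: per the labels' protocols and the submitters' processing notes, reads were filtered with fastp, aligned with HISAT2 to GRCh38 and counted per gene with HTSeq-count. The submitters' processing notes also name R 3.2.0. Aligner and counter versions, the gene annotation and the strand setting are not given in the sources used here, so reads of antisense or overlapping genes may be counted together. The authors also deposited FPKM values for the same genes and libraries. Dividing counts by FPKM and by the column total gave 1 length per gene, whole within 0.01 for 100% of the 20644 genes with counts and constant across libraries for the 18527 genes with counts in at least 2. The FPKM values therefore hold the same information as the counts, scaled to library totals and that length. The authors' own tests used DESeq2 per the series' design text, whose fold change wording mixes scales and was read here as 2-fold either way.

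The table lists 34415 genes, of which 13771 had no counts. The edgeR filterByExpr function (version 4.0.16; minimum count 10, minimum total 15) left 13412 genes with 99.96% of all counts. Total counts per library were 36342583, 37317797 and 40096810 for controls 1, 2 and 3 and 36721414, 33215130 and 39759533 for labelled knockdown 1, 2 and 3. The median standard error of a log2 fold change was 0.14, and the common biological coefficient of variation was 13.6%. Counts were scaled by TMM and compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are TMM-scaled, and log2 CPM values used a prior count of 2.

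A total of 34 gene lists were fixed before the data were examined, as were the groups, the main tests and most alternatives, and 31 lists had at least 5 tested members. They were tested with limma camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and adjusted over the lists. The same lists were tested with an estimated correlation and with fry. Mitochondrial genes were matched to the table's own symbols. Named genes followed a fixed rule: EFNA4; the 12 largest increases and the 12 largest decreases with adjusted p under 0.05, a mean of at least 10 CPM and groups that do not overlap; up to 4 members per list with the smallest p-values among those passing, or the single smallest if none passed; and genes of the series' title, among them CDH1, CDH2, VIM, SNAI1, SNAI2, ZEB1, AKT1 and PIK3CA. Not every gene chosen by this rule is named. The largest increases and decreases were chosen from 5293 eligible genes, which leave out pseudogenes, provisional symbols and XIST and TSIX. Genes named outside this rule in the closing section were chosen after their values were seen. Gene positions and biotypes are from the RefSeq annotation of GRCh38, matched for 32094 genes by symbol. Transcript GC content, coding and UTR lengths and exon counts are from GENCODE 29, with GC content for 95.7% of tested genes.

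The alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling and library totals in place of TMM; no count filter, or 1 CPM in at least 3 libraries; DESeq2's Wald test (version 1.42.0) and limma-voom; the replicate number as a block; limma on log2(FPKM + 1) with and without the filter and on log2(FPKM + 0.1); an offset for gene length; and leaving out each library. An offset for gene length and GC content together, list tests combining it with an estimated correlation, and a fit without control 1 and labelled knockdown 3 were added after seeing the data. The offset was a smooth of each library's log2 CPM, as the deviation from the gene's mean, on log length and GC content, fitted with mgcv 1.9.3 in R 4.3.3. Genes without a GC value took the median GC content and had a term of their own.

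The scripts were tested on simulated data drawn from the means, dispersions and depths of these libraries. For labelled knockdown against control, edgeR recovered 49.3%, 80.3% and 96.9% of genes changed 1.5-fold, 2-fold and 4-fold among 13252 genes, with 14 false calls, 8.59% of its calls. When the length and GC trend was simulated among 13253 genes, edgeR made 1071 false calls without the offset and 11 with it. The simulated trend was the same kind of smooth that the offset removes. The drop therefore tests the script and does not show that the offset corrects the real trend or spares real differences. Camera called the shifted list and 0 of the other lists. Genes were drawn independently in that simulation and without the length and GC trend, so it does not test camera on correlated genes. No library or gene with counts was left out of the main comparison other than by the count filter.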

Results

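The series profiled AGS cells, an established human gastric adenocarcinoma line, by RNA sequencing of total RNA extracts. Its stated subject is the ephrin ligand EFNA4 and its relation to epithelial-mesenchymal transition (EMT) and PI3K/AKT signalling. The 6 libraries fall into 2 groups of 3, labelled control and EFNA4 knockdown. Labels describe the controls both as wild type and as carrying a non-targeting construct, and the knockdown reagent both as siRNA and as shRNA. Gene counts summed to between 33215130 and 40096810 per library. No label says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Libraries of 1 group differed by more than sampling noise (smallest chi-square per gene 7.84, control 2 against control 3), so none was counted as a second deposit of another. This does not show that the samples are independent.

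The targeted gene was not lower in the libraries labelled EFNA4 knockdown. EFNA4, which encodes a membrane-anchored ligand of Eph receptor tyrosine kinases, lies on chromosome 1 from 155063740 to 155069553 on the plus strand (GRCh38) and has 4 annotated exons. Its level was 30.3 ± 1.25 CPM (SD, n = 3) in the control libraries and 42.3 ± 3.84 CPM (SD, n = 3) in the libraries labelled knockdown. The counts were 1211, 1169 and 1242 in controls 1, 2 and 3, and 1362, 1399 and 1641 in labelled knockdown 1, 2 and 3. EFNA4 was thus higher in the libraries labelled knockdown (log2 fold change 0.48, SE 0.11, adjusted p = 0.0048, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The exact two-sided permutation test of the log2 CPM values gave p = 0.1, the smallest p that 3 libraries against 3 allow. The authors' FPKM values, with 25.4 ± 1.01 in controls and 32.0 ± 2.15 in the libraries labelled knockdown (SD, n = 3), gave the same direction. They are the same counts scaled to library totals and gene length, not a separate measurement. With an offset for gene length and GC content the difference was 0.14 on the log2 scale (95% interval −0.07 to 0.35, adjusted p = 0.27, edgeR), and it no longer passed the threshold. The antisense gene DCST1-AS1 overlaps the first 252 bases of EFNA4 and had at most 113 counts in any library. Because the target goes against its label, groups are named here by their labels, and every direction below is the libraries labelled knockdown relative to the libraries labelled control.

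Of the 16 ephrins and Eph receptors tested, EFNA4 included, 7 were higher, 1 was lower and 8 were not called. EFNA3, the neighbouring ephrin gene, rose from 25.7 ± 1.72 to 42.5 ± 5.49 CPM (SD, n = 3), and the receptor EPHB4 rose from 177 ± 7.71 to 250.3 ± 16.8 CPM. EPHB3 rose by 0.58 on the log2 scale. EPHA4 was the member that fell, 1.51-fold. As a list the family did not pass the threshold (limma camera, adjusted p = 0.12), and its median of 0.30 was 0.094 with the length and GC offset, with 5 higher and 3 lower (camera adjusted p = 0.77). With an offset for length alone the list passed narrowly (camera adjusted p = 0.0497); with an estimated correlation it did not pass without an offset (adjusted p = 0.51) or with the length and GC offset (adjusted p = 0.85). Genes neighbouring EFNA4 on 1q22 included 7 higher and 0 lower of 16 tested, among them MTX1 (log2 fold change 0.67), KRTCAP2 (0.46) and CKS1B (0.39). This neighbour list passed camera (adjusted p = 0.011) but not with an estimated correlation (adjusted p = 0.52). With the length and GC offset its median was 0.05 and camera gave the opposite direction (adjusted p = 0.96).

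**Figure D1:**
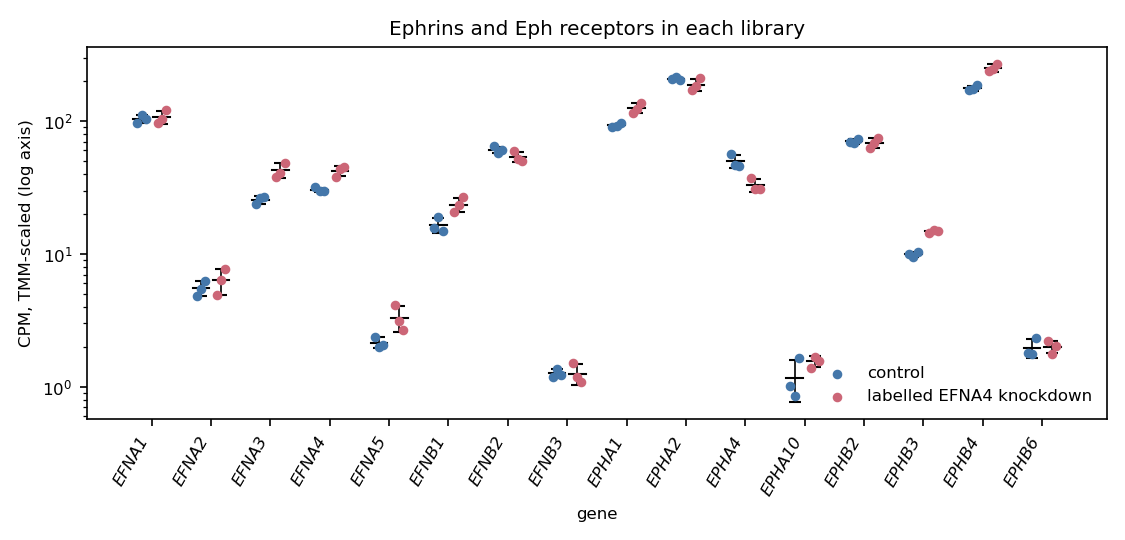
Level of each ephrin and Eph receptor with a mean of at least 1 CPM (y axis, log scale) in each library, with control libraries in blue and libraries labelled EFNA4 knockdown in red. Points are libraries, horizontal bars are means of 3 libraries and error bars are SD; all 3 red points of EFNA4 lie above its 3 blue points.

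Across the transcriptome, the groups differed broadly. Of 13412 genes tested, 6672 passed the threshold, 3226 higher and 3446 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among these, 972 differed at least 2-fold, and the large differences were mainly decreases, with 836 lower and 136 higher. The groups' libraries did not overlap for 61.8% of genes, where a chance ordering of 3 against 3 gives 10% on average. Genes vary together, so 1 ordering of the libraries can separate many genes at once. The excess over 10% is therefore not a test of chance. Scaling by library totals alone left 2128 higher and 4524 lower calls and shifted the median difference by −0.15, whereas the length and GC offset gave 3682 higher and 2209 lower. The number of 2-fold genes was 646 without control 1 and 542 with the length and GC offset.

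The 12 largest increases included PSG6, TAGLN and HSPA2. PSG6, a pregnancy-specific glycoprotein gene on chromosome 19 (42902086 to 42917894), was 3.77-fold higher, rising from 16.6 ± 0.84 to 62.7 ± 3.11 CPM (SD, n = 3). TAGLN, which encodes the actin-binding protein transgelin, was 3.74-fold higher, and PSG2 2.77-fold higher. The cytosolic chaperone gene HSPA8 rose from 966 ± 207 to 2714 ± 148 CPM, and HSPA2 was 3.50-fold higher. HSPA1A (3.03-fold) and HSPA1B (3.15-fold) also rose, but they are near-identical copies. How counting treated reads that match both is not given in the sources used here. The endoplasmic reticulum genes SDF2L1 and MANF were 3.37-fold and 2.52-fold higher. REG4, a secreted lectin-like protein gene, was 2.92-fold higher, the transcription factor gene CEBPA 2.73-fold higher, and the haem oxygenase gene HMOX1 2.61-fold higher.

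The 12 largest decreases included SLC7A11, DDIT4 and CTH. SLC7A11, the cystine transporter gene on chromosome 4 (138164097 to 138242349), fell from 58.2 ± 28.5 to 5.27 ± 1.05 CPM (SD, n = 3), 11.1-fold, with a wide spread among controls. DDIT4, an inhibitor of mTORC1, fell from 309 ± 15.5 to 48.2 ± 14.1 CPM, 6.41-fold. CTH, the cystathionine gamma-lyase gene, fell 4.68-fold. SPRED1 (4.44-fold) and ERRFI1 (3.96-fold), inhibitors of Ras-ERK and of EGFR signalling, fell as well, as did the transglutaminase gene TGM2 (4.44-fold) and the cytokine gene TNFSF15 (4.39-fold). SGPP1, MBNL2, KIF21B, SLC16A4 and KLF9 fell 4.62-fold, 4.29-fold, 4.06-fold, 4.04-fold and 4.06-fold. SGPP1, MBNL2 and SPRED1 also had a wide spread among controls, with control 1 highest. Their control levels were 90.4 ± 48.1, 47.8 ± 20.4 and 75.2 ± 34.7 CPM (SD, n = 3).

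**Figure D2:**
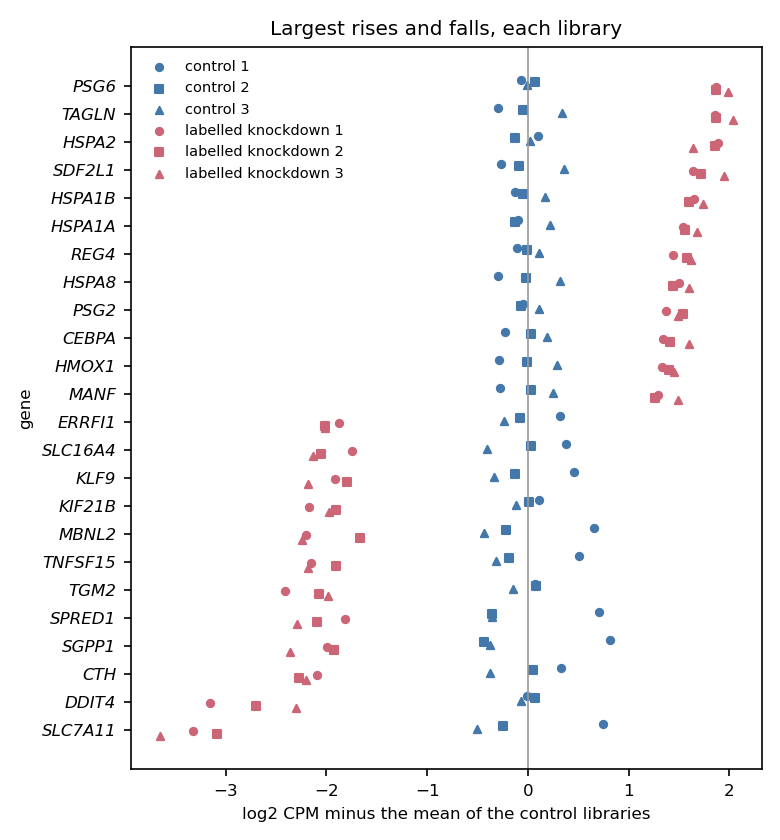
log2 CPM of the 12 genes with the largest increases and the 12 with the largest decreases (y axis) in each of 6 libraries, as the difference from the mean of the control libraries (x axis), with controls in blue and libraries labelled knockdown in red. Every red point lies on 1 side of all blue points of its gene, and SLC7A11 lies lowest, with a fitted difference of −3.47.

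Stress programmes moved in opposite directions. Of 25 tested genes of the integrated stress response, the programme driven by ATF4, 22 were lower and 0 higher (24 lower when adjusted over the list alone), with a median log2 fold change of −0.99. PSAT1, of serine synthesis, fell from 777 ± 152 to 202 ± 9.31 CPM (SD, n = 3). MTHFD2, of mitochondrial folate metabolism, fell 3.13-fold, and the glycyl-tRNA synthetase gene GARS1 2.07-fold. The list passed camera (adjusted p = 4.27e-12; adjusted p = 0.26 with an estimated correlation). By contrast, 13 of 15 heat shock genes were higher and 0 lower, including STIP1 (1.69-fold), and the median was 0.53 (camera adjusted p = 4.21e-06; adjusted p = 0.26 with an estimated correlation). Of 23 genes of the unfolded protein response of the endoplasmic reticulum, 13 were higher and 6 lower (camera adjusted p = 0.0074; adjusted p = 0.26 with an estimated correlation). Those that rose included the folding factors CRELD2 (2.44-fold) and PDIA4 (1.82-fold). With the length and GC offset the medians of these lists were −1.01, 0.56 and 0.53, in the order given.

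In the lists of ERK pathway outputs, immediate early genes, YAP-TEAD targets and Wnt-beta-catenin targets, most called genes were lower. Among 18 outputs of the ERK pathway, 16 were lower and 0 higher (16 lower and 1 higher when adjusted over the list alone), with a median of −0.93. The transcription factor genes ETV5, EGR1 and ETV4 fell 3.39-fold, 3.53-fold and 2.37-fold, and PHLDA1 fell 3.94-fold. Of 15 immediate early genes, 9 were lower, with KLF6 (1.96-fold) and KLF4 (1.95-fold) among them, and 1 was higher, BTG2 (1.69-fold), which is also a p53 target. The YAP-TEAD target list had 11 lower and 0 higher of 16, including ANKRD1 (2.94-fold), PTPN14 (1.95-fold), CCN2 (1.77-fold) and AJUBA (1.58-fold). The Wnt-beta-catenin target list had 10 lower and 1 higher of 15, including PROX1 (7.09-fold lower), DKK1 (28.2 to 11.3 CPM), TNFRSF19 (1.70-fold) and MYC (1.62-fold). These 4 lists passed camera with adjusted p of 2.53e-08, 0.0027, 9.77e-05 and 0.0024, in the order given, and each had adjusted p = 0.26 with an estimated correlation. Their medians with the length and GC offset were −0.96, −0.52, −0.46 and −0.40.

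Interferon-response genes were also lower, 24 of 36 with 0 higher (25 lower when adjusted over the list alone; median −0.60). IFI44 fell 3.07-fold, IFI44L 5.00-fold, TRIM22 3.48-fold, and DDX58, which encodes the RNA sensor RIG-I, 2.02-fold. The list passed camera (adjusted p = 9.91e-08; adjusted p = 0.26 with an estimated correlation), and its median with the length and GC offset was −0.50. In the inflammatory list of NF-kB targets, 8 of 21 were lower and 2 higher, without passing camera (adjusted p = 0.32). CXCL1 (2.63-fold), PTGS2 (3.09-fold) and CXCL3 (1.92-fold) fell, each from a control level under 4 CPM, and NFKBIE rose 1.87-fold. With the offset this list passed (median −0.27, camera adjusted p = 0.014), but not with the offset and an estimated correlation (adjusted p = 0.21).

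Most genes in the lists for cholesterol synthesis, oxidative phosphorylation, ribosomal proteins and S phase were higher. Of 25 cholesterol synthesis genes, 17 were higher and 1 lower, with a median of 0.56 (camera adjusted p = 9.33e-06; adjusted p = 0.26 with an estimated correlation). MVK, mevalonate kinase, rose from 27.2 ± 4.95 to 68.0 ± 3.89 CPM (SD, n = 3), and NSDHL was 2.24-fold higher, DHCR7 1.99-fold and ACAT2 1.68-fold. In the fatty acid synthesis list, 4 of 12 were higher, with FASN 1.72-fold, and 5 lower, with ACSL1 1.63-fold and ACSL4 2.17-fold (camera adjusted p = 0.88). ELOVL6 fell by 0.43 on the log2 scale, but its difference was 0.06 with the length and GC offset. Nuclear genes of oxidative phosphorylation were higher in 29 of 39 and lower in 1 (31 higher when adjusted over the list alone), led by UQCRC1 (1.58-fold), COX6B1 (1.64-fold), NDUFB10 (1.61-fold) and UQCRQ (1.54-fold); camera gave adjusted p = 2.90e-07, and adjusted p = 0.51 with an estimated correlation. Of 75 ribosomal protein genes, 57 were higher and 0 lower, among them RPS15 (1.56-fold), RPS10 (2.03-fold) and RPS26 (1.63-fold), with camera adjusted p = 2.98e-12, and adjusted p = 0.51 with an estimated correlation. In these last lists, whose members are short, medians of 0.44 and 0.39 were 0.29 and 0.22 with the length and GC offset.

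Of 33 S phase genes regulated by E2F, 19 were higher and 3 lower (20 higher when adjusted over the list alone). GINS2 was 2.01-fold higher, FEN1 1.93-fold, MCM5 1.69-fold and TYMS 1.66-fold (camera adjusted p = 2.09e-05; adjusted p = 0.26 with an estimated correlation). Genes of G2 and M phase numbered 12 higher and 4 lower of 35, with CDC20 (1.87-fold), BIRC5 (1.65-fold), CDCA8 (1.61-fold) and UBE2C (1.58-fold) higher. That list did not pass camera (adjusted p = 0.29), and its median (−0.02) and mean (0.07) differed in sign. With the length and GC offset 24 of its members were higher and 1 lower, and the list passed (camera adjusted p = 3.30e-05), but not with the offset and an estimated correlation (adjusted p = 0.38).

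The genes of the series' title gave a divided picture. For EMT, the epithelial cadherin gene CDH1 was at 9.60 ± 0.67 CPM in controls and 8.28 ± 1.02 CPM in the libraries labelled knockdown (SD, n = 3), a difference that did not pass the test (adjusted p = 0.25, edgeR). VIM, the mesenchymal filament gene vimentin, fell from 2.36 ± 0.25 to 1.10 ± 0.16 CPM (adjusted p = 0.0041, edgeR). The EMT transcription factor gene SNAI1 stood at 7.76 ± 1.31 and 10.2 ± 1.43 CPM (adjusted p = 0.075), and ZEB1 at 0.43 ± 0.24 and 0.26 ± 0.17 CPM (adjusted p = 0.36). CDH2 had 1 count and SNAI2 6 counts in all libraries together, too few to test. Among 36 epithelial genes 11 were higher and 12 lower, with CLDN1 (3.53-fold), PKP2 (1.73-fold) and TJP1 (1.67-fold) lower and MARVELD3 (1.66-fold) higher. Among 25 mesenchymal genes 7 were higher and 8 lower, with TAGLN, MYL9 (1.82-fold) and COL5A1 (4.20-fold, from 0.26 CPM) higher and ITGB1 (1.62-fold) lower. Neither list passed camera (adjusted p = 0.9996 and 0.78). In both, the median and the mean differed in sign.

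PI3K-AKT-mTOR components were similarly mixed, with 11 higher and 17 lower of 43 (12 and 19 when adjusted over the list alone; camera adjusted p = 0.30). AKT1 was 1.33-fold higher (155 ± 12.8 to 207 ± 21.7 CPM, SD, n = 3; adjusted p = 0.0081, edgeR). PIK3CA was 1.85-fold lower (5.28 ± 1.12 to 2.87 ± 1.31 CPM; adjusted p = 0.035, edgeR). The receptor genes ERBB3 (2.60-fold) and MET (1.95-fold), the adaptor gene IRS1 (2.43-fold) and the mTOR inhibitor gene DEPTOR (7.66-fold) fell. DEPTOR was at 9.23 ± 4.47 CPM in controls, with control 1 highest, and 1.21 ± 0.42 CPM in the libraries labelled knockdown (SD, n = 3). With the length and GC offset the PIK3CA difference was −0.10 (adjusted p = 0.74, edgeR), and the list had 13 higher and 10 lower. PIK3CA also lost its call without labelled knockdown 1 or 3 (adjusted p = 0.099 for each, edgeR). FOXO target genes, which active AKT represses, had 15 lower and 1 higher of 21 (16 and 2 when adjusted over the list alone). TNFSF10 (3.79-fold), CDKN1B (2.18-fold) and TXNIP (1.85-fold) fell, beside ERBB3. The FOXO list passed camera (adjusted p = 0.00012; adjusted p = 0.26 with an estimated correlation), and its median of −0.69 was −0.36 with the offset.

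Further lists held members moving both ways and did not pass camera. In the glycolysis and hypoxia list 14 of 28 were higher and 9 lower (adjusted p = 0.35), and its median (0.29) and mean (−0.02) differed in sign. Its 4 members with the smallest p-values, DDIT4, VEGFA (2.44-fold), HK2 (2.63-fold) and SLC2A3 (1.73-fold), all fell although more members rose than fell. p53 targets numbered 8 higher and 7 lower of 26 (adjusted p = 0.22), with FDXR (2.04-fold), BAX (1.72-fold) and AEN (1.58-fold) higher. TGF-beta targets numbered 5 higher and 8 lower of 17 (adjusted p = 0.68), with ID3 2.44-fold higher and COL4A2 2.09-fold and TGIF1 1.48-fold lower. In the integrin, laminin and focal adhesion list 6 were higher and 11 lower of 30 (adjusted p = 0.50), with ITGA2 (3.79-fold) and ITGA6 (2.24-fold) lower and ZYX (1.56-fold) higher. Matrix proteases and their inhibitors numbered 3 higher and 5 lower of 14 (adjusted p = 0.27), with ADAM17 (2.05-fold), PLAT (2.09-fold) and ADAM10 (1.86-fold) lower; with the length and GC offset this list passed (adjusted p = 0.0081; adjusted p = 0.26 with an estimated correlation as well) and ADAM10 no longer did. Gastric and intestinal differentiation genes numbered 5 higher and 7 lower of 17 (adjusted p = 0.36), with TSPAN8 (2.01-fold), CEACAM5 (2.41-fold) and AGR2 (5.33-fold, from 1.75 CPM) lower. Apoptosis genes numbered 7 higher and 9 lower of 27 (adjusted p = 0.60), with BAD (1.73-fold) higher and PMAIP1 (2.67-fold) and CFLAR (1.43-fold) lower, of which CFLAR was at −0.01 with the offset. Lysosome and autophagy genes numbered 11 higher and 6 lower of 22 (adjusted p = 0.27), with NEU1 (1.71-fold), GLA (1.72-fold) and SQSTM1 (1.59-fold) higher and ULK1 (1.54-fold) lower.

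Mitochondrially encoded genes were higher in 5 of 13 and lower in 0 (camera adjusted p = 0.053), led by ND3 (1.41-fold), ND1 (1.31-fold), the cytochrome oxidase subunit gene COX2 (1.28-fold) and CYTB (1.24-fold). Their share of all counts was 5.53 ± 0.15% in controls and 5.48 ± 0.45% in the libraries labelled knockdown (SD, n = 3; exact permutation p = 0.9). Scaled by library totals, ND3 and ND1 were still called, but COX2 and CYTB were not (adjusted p = 0.053 and 0.087, edgeR). Replication-dependent histone genes, 5 higher and 1 lower of 9 (adjusted p = 0.052), included H1-2 (1.95-fold), H2BC5 (2.13-fold), H2BC21 (1.81-fold) and H3C10 (2.34-fold). The summed level of the list differed less. Scaled by library totals, it was 42.7 ± 4.15 CPM in controls and 49.0 ± 1.24 CPM in the libraries labelled knockdown (SD, n = 3; exact permutation p = 0.1). Markers of fibroblasts, endothelium and blood cells had too few tested members for a list test (3, 1 and 4). Their highest member reached 24.8, 27.8 and 43.8 CPM in any library. Where no count adjusted over the list alone is given for a list, it moved the numbers above by at most 1 gene.

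**Figure D3:**
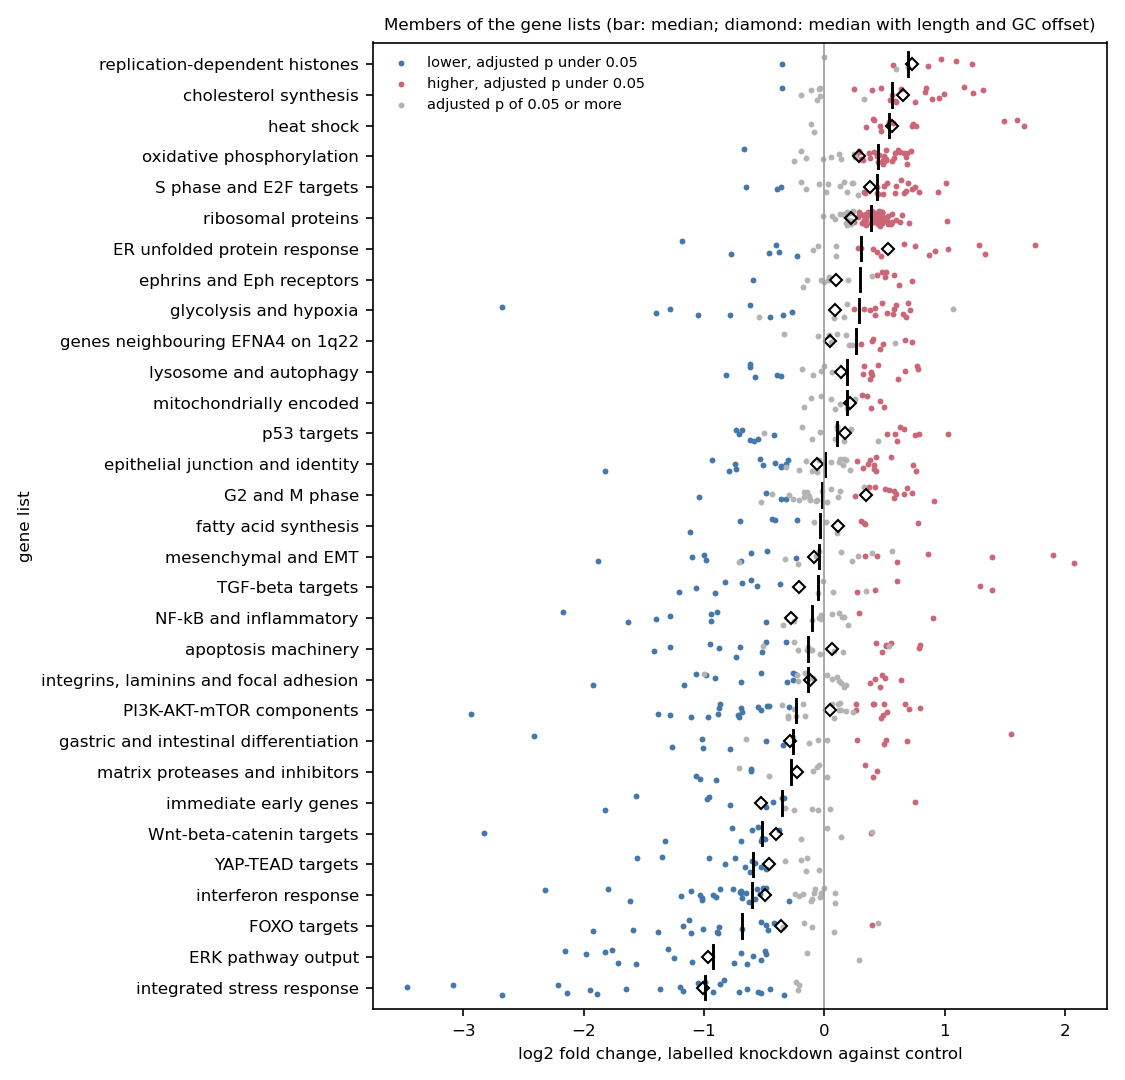
log2 fold change of each tested member (x axis) of 31 gene lists (y axis), with members passing the edgeR test in red (higher in the libraries labelled knockdown) or blue (lower) and the others in grey. Vertical bars are list medians and open diamonds the medians with an offset for gene length and GC content; the integrated stress response list lies lowest, at −0.99 and −1.01.

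The differences followed gene length and GC content. The median log2 fold change was 0.27 among the shortest eighth of genes and −0.42 among the longest. Across genes, the difference in mean log2 CPM had Spearman correlations of −0.34 with length (13412 genes) and 0.58 with transcript GC content (12829 genes). Genes are not independent replicates. Libraries of 1 group differed along the same axes. Control 1 minus the mean of controls 2 and 3 correlated 0.33 with length and −0.60 with GC content, and labelled knockdown 3 minus the mean of labelled knockdown 1 and 2 correlated −0.36 and 0.58. Spread among controls along the group difference went beyond length and GC content. Control 1 minus control 3 correlated −0.49 across genes with the mean of labelled knockdown 1 and 2 minus control 2, and −0.30 with length and GC content removed (Spearman). On the first principal component, with 68.3% of the variance, controls 1, 2 and 3 lay at −54.0, −27.9 and −20.7 and labelled knockdown 1, 2 and 3 at 27.8, 28.4 and 46.5. Measures of the libraries as a whole differed too. Genes detected numbered 17508 ± 130 in controls and 16982 ± 74.0 in the libraries labelled knockdown, and the count-weighted median gene length was 3294 ± 122 and 2958 ± 88.3 bases (SD, n = 3). Ribosomal protein genes took 6.99 ± 0.57% and 8.27 ± 0.50% of counts, and the 10 most abundant genes 6.56 ± 0.12% and 6.89 ± 0.21% (SD, n = 3). Each of these 4 measures had exact permutation p = 0.1, the smallest possible. With an offset removing both trends, 5891 genes passed, 63.7% of the original calls kept their direction and call, and 47 were called in the opposite direction.

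**Figure D4:**
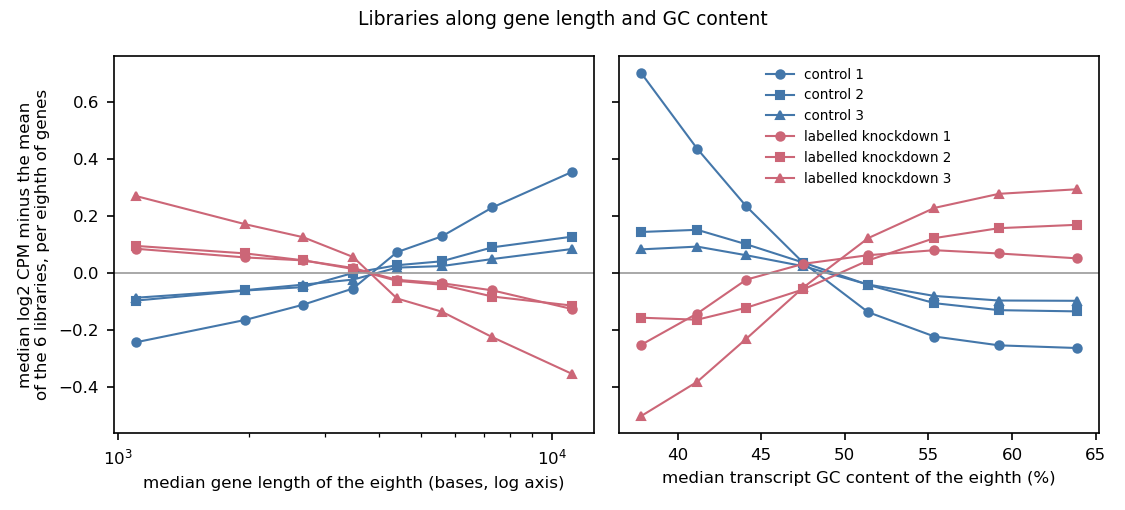
Median log2 CPM of each library minus the mean of 6 libraries (y axis) in eighths of the tested genes by gene length (left, bases, log axis) and by transcript GC content (right, percent), with controls in blue and libraries labelled knockdown in red. Control 1 and labelled knockdown 3 lie at opposite ends, at 0.70 and −0.50 in the eighth with the lowest GC content.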

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

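The offset for length and GC content, alone and with an estimated correlation, and the fit on 4 libraries, without control 1 and labelled knockdown 3, were chosen after seeing the data. The number of genes past the threshold stayed within 1.5 times its value of 6672 in every setting, from 4673 (without labelled knockdown 3) to 7479 (replicate block). The number of genes past threshold and at least 2-fold apart, 972, was 308 with limma on log2(FPKM + 1), 291 without the filter, 542 with the length and GC offset and 585 on 4 libraries; leaving out 1 library gave 646 (without control 1) to 1255 (without control 3). The pseudocount shrinks folds of low genes; for the others the cause was not tested. The higher share of calls, 48.4%, was 32.0% with library totals, 33.7%, 33.5% and 36.5% with the FPKM fits, 59.8% with the length offset and 62.5% with the length and GC offset. EFNA4 was above 0 in every setting, at 0.14 with the length and GC offset (adjusted p = 0.27, edgeR; other model fits 1.49e-04 to 0.025) and 0.48 in the exact permutation test, which cannot pass with 3 against 3. Of the 14 lists called by camera, 0 passed with an estimated correlation, with or without the length and GC offset, and fry, which compares no list with other genes, called 24. With the length and GC offset ELOVL6 went to 0.063 and the 1q22 neighbour list to a median of 0.046 with camera's direction opposite, both then uncalled. Besides EFNA4 and ELOVL6, 6 genes of the naming rule lost their call, among them TGIF1, KRTCAP2, ADAM10, CFLAR and PIK3CA. Calls were also lost for 7 such genes with the length offset, 4 with log2(FPKM + 1), 7 with it unfiltered, 3 with log2(FPKM + 0.1), 2 with library totals and PIK3CA on 4 libraries. The 1q22 list lost its call with the length offset, on 4 libraries and with fry. Values uncalled before and after were counted as unchanged even where the sign differed. The replicate numbers gave no clear pairing of the libraries. Deviations of same-numbered libraries correlated 0.19, −0.13 and 0.29, and only replicate 3 correlated best with its own number. Such correlations do not exclude a pairing. The replicate block added calls for SNAI1 and the mitochondrially encoded list and removed none among named genes and lists. Genes below the count filter, such as CDH2, could not be compared at this depth.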

Other observations

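The after-the-fact tests here are the offset for length and GC content, the hidden-fall test of EFNA4 and the within-group length test. Others are the stress-list tests with that offset and without control 1, the whole-chromosome tests and the choice of gene families. The list tests combining the offset with an estimated correlation were added then too. Genes sharing a symbol prefix were grouped into 229 families, none of which passed with an estimated correlation. Of 14 Krüppel-like factor genes, which encode zinc-finger transcription factors, 11 were lower and 1 higher, including KLF2 (log2 fold change −0.79), KLF5 (−1.14) and KLF10 (−1.24), and KLF16 rose by 0.46. Of 52 symbols with the prefix of the large mitochondrial ribosomal subunit, 3 of them noncoding neighbours without a call, 35 were higher and 2 lower, with MRPL27 at 0.83 and MRPL49 at 0.84. Of 29 with the prefix of the small subunit, 1 of them a noncoding neighbour without a call, 15 were higher and 3 lower, with MRPS6 at 1.00. Both groups kept their direction with the length and GC offset (medians 0.27 and 0.36). These 3 families passed camera, with adjusted p of 0.0012, 1.35e-05 and 0.0076 in the order given, and had adjusted p = 0.87 with an estimated correlation. They were not the only ones. The RPL, RPS, NDUFA and NDUFB families also passed camera (adjusted p of 5.30e-06, 4.08e-05, 0.0076 and 0.022). With the length and GC offset further families passed, among them POLR, IFI, HSPA and MCM.

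Among 8 CXCL genes, which encode chemokines, 7 were lower and 1, CXCL16, was higher (0.47); with the length and GC offset 4 were lower and 1 higher. Of 10 symbols with the SOX prefix, 1 of them the uncalled antisense RNA SOX9-AS1, 6 were lower and 1 higher (6 and 0 with the offset). SOX21 fell by 3.52 and SOX9 by 0.80 on the log2 scale. Of 8 KLK genes, which encode secreted serine proteases, 5 were lower and 0 higher (7 and 0 with the offset), including KLK6 (−0.63). These families did not pass camera (adjusted p of 0.13, 0.13 and 0.10) but did so with the length and GC offset (adjusted p of 0.043, 0.0079 and 0.00080), and again not with an estimated correlation (adjusted p = 0.87 without the offset and 0.75 with it). POLR2A, the gene of the largest RNA polymerase II subunit, rose by 1.09.

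EFNA4 was not lower in the libraries labelled as its knockdown. With the offset the lower 95% bound of the difference was −0.074, which excludes a fall of 0.5. This argues against a hidden fall only as far as the offset corrects the length and GC trend, which is not shown. The limit of 0.5 for a hidden fall was written after the data were seen. An exchange of 1 library between groups is argued against, since 0 libraries correlated best with a library of the other group. Antisense reads stay open: DCST1-AS1 reached at most 0.24 of the excess in EFNA4 CPM, under the limit of 0.5 set in advance, but its own counts do not measure antisense reads assigned to EFNA4, and the strand setting is not known. Exchanged labels for all libraries could not be told apart from other explanations. With the offset, exchange was to give a whole interval above 0.5, and an upper bound below 0 was to speak against it. The upper bound was 0.35, so neither was met, and both a small and no difference remain possible. Without the offset the 95% interval was 0.25 to 0.72 (edgeR). The hidden fall was judged by a different limit, whether the lower bound excluded a fall of 0.5. A knockdown that acts on protein but not on RNA, or that had faded by harvest, was not tested.

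Long and AT-rich transcripts were lower in the libraries labelled knockdown. Control 1 alone is argued against, as the longest eighth of genes still had a median of −0.31 without it. A difference in library or RNA quality is consistent with the correlation of 0.33 between gene length and the gap of control 1 from its own group, which the label cannot produce. Fragmentation acting along the whole transcript is consistent with the standardised coefficient of −0.18 for coding length, beside 3' UTR length and GC content, but the coefficient for GC content was larger (0.57). The label itself, as a biological cause of the trend, stays open.

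In the integrated stress response list 22 of 25 genes were lower, while 13 of 15 heat shock genes and 13 of 23 genes of the unfolded protein response were higher and 6 of the latter lower; none of these 3 lists passed with an estimated correlation (adjusted p = 0.26). The length and GC trend is argued against, since the stress list had a median of −1.01 with the offset, and so is control 1 alone, with −0.93 without it. The state of the cultures (medium, density, time of harvest) cannot be told apart from the label: the controls' range was 0.17 of the group difference, between the limits set for either reading, and groups handled separately would look the same.

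A copy number difference between the cultures was tested as another hypothesis. After the offset, 3 runs of 50 neighbouring genes lay beyond the limit from 200 gene-order permutations, on chromosomes 12 (−0.29 and −0.28) and 18 (0.28), below the size of 0.3 set in advance, so that test left it open. A whole-chromosome test was then added, and 3 chromosomes lay beyond its limit with groups that did not overlap, as a copy number difference could give: 4 (−0.11), 18 (0.15) and 16 (0.06). The lack of overlap does not set these 3 apart. Groups also did not overlap on chromosomes with very small shifts, such as 9 (0.0013) and 6 (−0.0020). The limit itself comes from permutations that treat genes as independent. The direction on chromosome 18 rests on the offset, since its shift was −0.09 without it, and the shifts of chromosomes 4 and 16 were larger without it, at −0.39 and 0.26. A second rule, requiring a whole-chromosome shift of at least 0.25, was drawn up when the largest shift, 0.15, was already known, and for a time it replaced the first rule. No chromosome met it, and because of that order the first rule was put back and the second is given no weight.

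With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For each of the counts, 1 of the 10 splits, the real one, gave a result as large. The real split called 6672 genes, 972 of them at least 2-fold apart, and the highest of the others called 0 (edgeR). For lists the real split called 14 and the highest of the others 13, so camera with its preset correlation called nearly as many lists where no gene passed. Each of the other splits mixes libraries of both labels. Part of the group difference thus stays between its groups, and the rest widens the spread within them. Counts from these splits, of genes or of lists, are therefore not a rate of calls without a difference.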
